A study of Mus musculus with 9 samples.

How the data were processed

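RNA abundance was measured in primary cortical neurons of C57BL/6 mouse embryos, taken on embryonic day 15. Per the labels' protocols, the cultures were infected on day 5 for 4 h with a lentivirus carrying a short hairpin RNA (shRNA), kept for 6 more days and harvested on day 11. The shRNA was either a control hairpin (shCont) or 1 of 2 hairpins against Tdp-43 (shTdp-43-1 and shTdp-43-2), with 3 arrays in each of the 3 groups. The series' design text speaks of motor neurons and of a harvest 11 days after transfection, while the sample labels speak of cortical neurons and of day 11 of culture; the sample labels were followed. For each array, 100 ng of RNA was used for the Affymetrix Mouse Exon 1.0 ST array, whose probe sets lie along the exons of a gene, so that they can be averaged over the gene or read one by one.

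The deposited file holds a log2 value per probe set and array, made by the authors with RMA in Affymetrix Expression Console at the exon level, per the labels and the submitters' processing notes, which also name the genome build mm9. RMA subtracts background, brings the probe values of all arrays to one distribution and summarises the probes of a set. A change shared by most probes of an array is thus largely removed, and dim probe sets are pulled towards the background level. Medians over all probe sets still ranged from 6.04 on shCont replicate 1 to 6.19 on shTdp-43-1 replicate 2. Software versions are not given in the sources used here. The table holds 1256831 probe sets on 9 arrays, of which 20744 (1.65%) read exactly 0 on all 9 arrays and none of these has a gene name. No per-sample column was left unused. The number of arrays, 3 per group, limits the precision.

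Probe sets were named through the platform annotation: 318760 have 1 gene symbol, 6684 have several and 931387 have none. Symbols were brought up to date through a RefSeq table (assembly GRCm38.p6, used for names only), in which 18006 symbols were current, 4227 were updated from a synonym and 63 were kept as given. Exon coordinates were not used here, so exons are identified by probe set ID. A probe set was kept where its mean log2 value over all arrays reached the median of the table, 6.07. The value of a gene is the mean log2 value of its kept probe sets that name that gene alone, and genes with at least 3 such probe sets were tested. This gave 16770 genes from 248701 probe sets, with a median of 12 probe sets per gene.

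All 3 groups were fitted in one linear model with limma (lmFit and eBayes; 6 residual degrees of freedom), so that they share one estimate of the spread. The contrasts were each hairpin minus shCont, shTdp-43-2 minus shTdp-43-1, and the mean of both hairpins minus shCont. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05; adjusted p-values of genes, lists and probe sets come from limma. The smallest two-sided p of an exact permutation test of 3 arrays against 3 is 0.1, so no single value was tested that way. Calls shared by both hairpins were set beside the overlap of independent lists. They were also set beside 100 simulations of unchanged groups against the same control arrays, with noise drawn independently for each gene and array.

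The 29 gene lists (8 of cell type markers, 21 of functions and of known Tdp-43 targets) hold 478 genes, of which 441 were tested; the others are not analysed here. Each list was tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, and again with an estimated correlation. It was also tested with limma's fry. Its directional p asks whether the genes of a list move, on balance, one way, and its mixed p asks whether they change in either direction; neither compares the list with other genes. Exon usage was tested with limma's diffSplice, which compares the change of each probe set with the change of the rest of its gene, over the same 248701 probe sets. Each probe set was also tested alone, over all 628416 probe sets at or above the median of the table, named or not.

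The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Tardbp and the 15 genes higher and 15 lower in both hairpins with the largest smaller change. It takes the 5 genes higher and 5 lower between the hairpins with the largest change. It also takes 10 exon probe sets with higher and 10 with lower usage in both hairpins, at most 1 per gene. The limit per gene was applied within each direction, which the fixed wording did not say, so Slc8a1 was named in both. Of each list it takes at most 4 called members, by the size of their change in the mean of the hairpins. Members of the 3 lists of Tdp-43 targets are taken as well where their value is the point. Clone-like names and small RNA genes were passed over. Any other gene in the text was chosen after its values were seen, and the text says so. The alternatives were 2 other dim filters and none, median polish in place of the mean, quantile normalization of the gene values, centring of each array on its median, eBayes with trend and robust, only the compared groups in the fit, the replicate number as a block, 1 probe set as the minimum, other list tests, and leaving out each array in turn. A pair of further alternatives was added after seeing the data: leaving out 2 arrays that deviate together, and testing usage with each probe set's own spread instead of the spread shared by the probe sets of a gene.

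The steps were tested on simulated data with known changes. These were built from the real means and spreads, with noise independent between genes, probe sets and arrays. For shTdp-43-1 against shCont, 90 of 100 genes changed by 1 log2 and 57 of 100 changed by 0.5 log2 were recovered, with 6 unchanged genes called among 16770. For calls in both hairpins these numbers were 89 of 100, 49 of 100 and 0. For usage in both hairpins diffSplice recovered 83 of 100 probe sets changed by 1 log2 and 100 of 100 changed by 2 log2, and called 103 other probe sets among 248701. With each probe set's own spread the same step recovered 29 of 100 and 95 of 100 and called 2 others. For the lists, 1 of 1 shifted list was recovered and 0 of the others were called. Deviations shared by many genes, as on the real arrays, are not covered by these counts. Over 100 groupings of the real arrays, 95 had at least 1 list called, with a median of 4 over those other than the real one. The work used R 4.3.3, limma 3.58.1, statmod 1.5.0 and data.table (1.17.8). The labels do not say that the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.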

Results

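The series asked which transcripts and exons depend on Tdp-43, an RNA-binding protein that controls splicing and RNA stability and is encoded by Tardbp, in cultured mouse cortical neurons. Exon-level arrays measured 3 samples with a control hairpin and 3 with each of 2 hairpins against Tdp-43. Log2 values of the tested genes had similar medians on all arrays, from 8.75 on shTdp-43-2 replicate 3 to 8.94 on shCont replicate 1. Across genes, arrays of one group correlated with r from 0.985 to 0.994, and the lowest correlation between any pair of arrays was 0.966. The first principal component held 40.6% of the variance and put the controls at one end and shTdp-43-2 at the other, with shTdp-43-1 in between. The second held 24.4% and had shTdp-43-1 replicates 2 and 3 at its lower end.

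Tardbp fell with both hairpins. Its log2 value was 9.92 ± 0.148 (SD, n = 3) in shCont, 8.21 ± 0.352 (SD, n = 3) in shTdp-43-1 and 8.23 ± 0.337 (SD, n = 3) in shTdp-43-2. This is 30.4% of the control level with shTdp-43-1 (log2 change -1.72 ± 0.186 SE, limma adjusted p = 0.000349) and 30.9% with shTdp-43-2 (log2 change -1.69 ± 0.186 SE, limma adjusted p = 0.000109). All 16 probe sets of Tardbp were lower with each hairpin. Between the hairpins Tardbp differed by 0.03 on the log2 scale, with a 95% interval from -0.38 to 0.43 (limma adjusted p = 0.956).

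**Figure D1:**
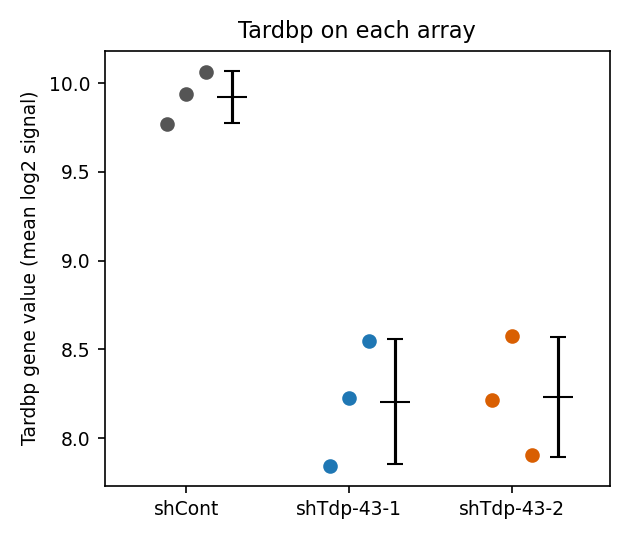
Tardbp gene value (mean log2 signal of 16 probe sets, vertical axis) on each array of the 3 groups (horizontal axis); points are arrays and the dash with bars is the group mean ± SD (n = 3). All 6 knockdown arrays lie below all 3 control arrays, with group means of 8.21 and 8.23 against 9.92.

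Rasgrf1, a Ras exchange factor of neurons, rose by log2 1.57 ± 0.124 (SE, n = 3 against 3) with shTdp-43-1 and by 1.91 ± 0.124 with shTdp-43-2. Stx1a, the syntaxin of synaptic vesicle fusion, rose 2.43-fold and 2.10-fold with the same hairpins. Camk2n1, an inhibitor of the kinase CaMKII, rose 2.05-fold and 2.19-fold, and Penk, the precursor of the enkephalin peptides, rose 2.27-fold and 2.06-fold. Gng7, a G protein gamma subunit, rose by log2 1.17 and 1.26.

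Agt, which encodes angiotensinogen, fell by log2 1.19 ± 0.140 (SE) with shTdp-43-1 and by 2.20 ± 0.140 with shTdp-43-2 (limma adjusted p = 0.000558 and 6.6e-06). Kera, which encodes the proteoglycan keratocan, changed by log2 -1.19 and -1.92, and Trhr, the receptor for thyrotropin-releasing hormone, by -1.54 and -1.18. Cps1, an enzyme of the urea cycle, changed by -1.36 and -1.10, and the urea transporter Slc14a1 by -1.03 and -1.07. Cnn2, an actin-binding calponin, and Tarsl2, a threonyl-tRNA synthetase, fell to a similar extent with each hairpin (Cnn2 -1.23 and -1.29, Tarsl2 -1.27 and -1.21). Papss2, which makes the donor of sulfate groups, changed by -0.90 and -1.65. Washc4, a subunit of the WASH complex of endosomes, changed by -0.96 ± 0.128 and -0.99 ± 0.128.

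The other genes named by the rule were, among those that rose, Qpctl (log2 1.28 and 1.35), Mrps36 (1.26 and 1.66), Fam81a (1.12 and 1.38), Ilk (1.06 and 1.40), Rflnb (1.00 and 1.48), Chodl (0.98 and 1.26), Tceal5 (1.00 and 0.96), Tceal6 (1.17 and 0.96), Slc45a1 (1.02 and 0.94) and Taf9b (0.94 and 1.09). Among those that fell were Gpr21 (-1.03 and -0.98), Kcne1l (-1.16 and -0.98), Padi2 (-0.95 and -1.27), Kdm7a (-0.94 and -1.17) and Nkap (-0.92 and -1.42). Of these genes and those described before them, Agt, Papss2, Kera, Nkap, Rflnb and Mrps36 also differed between the hairpins at an adjusted p under 0.05. In the mean of the hairpins 4 of 11 markers of fibroblasts and pericytes fell (camera adjusted p for the list = 0.294). Called lower with both hairpins were 2 of the 11. Of 14 astrocyte markers Aqp4 fell and Vim rose in the mean, and 12 were not called. With shTdp-43-1 alone 0 astrocyte markers rose.

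In all, 1081 of 16770 genes were called in the same direction with both hairpins, 495 higher and 586 lower. Lists of the same lengths drawn independently would share 67.1 and 141 genes in these directions, and 21 genes were called in opposite directions (11 higher with shTdp-43-1 and 10 higher with shTdp-43-2). Both comparisons used the same 3 control arrays. Across genes the log2 changes of both hairpins correlated with r = 0.621, against 0.502 on average in 100 simulations of unchanged groups, and their covariance was 0.0436 against 0.00612. The same sign was seen in 74.8% of genes against 66.7%, and the simulations called 0 genes in both on average. The controls are too few to be split, so part of the excess may come from the shared controls. The simulated noise was independent between genes, while deviations of the real arrays correlated by up to 0.681 between groups. The simulations therefore cannot show how many shared calls such deviations would yield. With each array centred on its median the shared calls split into 798 higher and 461 lower, against 495 and 586. The count fell to 491 without shCont replicate 1, 590 without shCont replicate 2, 679 without shTdp-43-1 replicate 2, 673 without shTdp-43-1 replicate 3 and 710 without shTdp-43-1 replicate 2 and shTdp-43-2 replicate 3, a choice made after seeing the data.

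**Figure D2:**
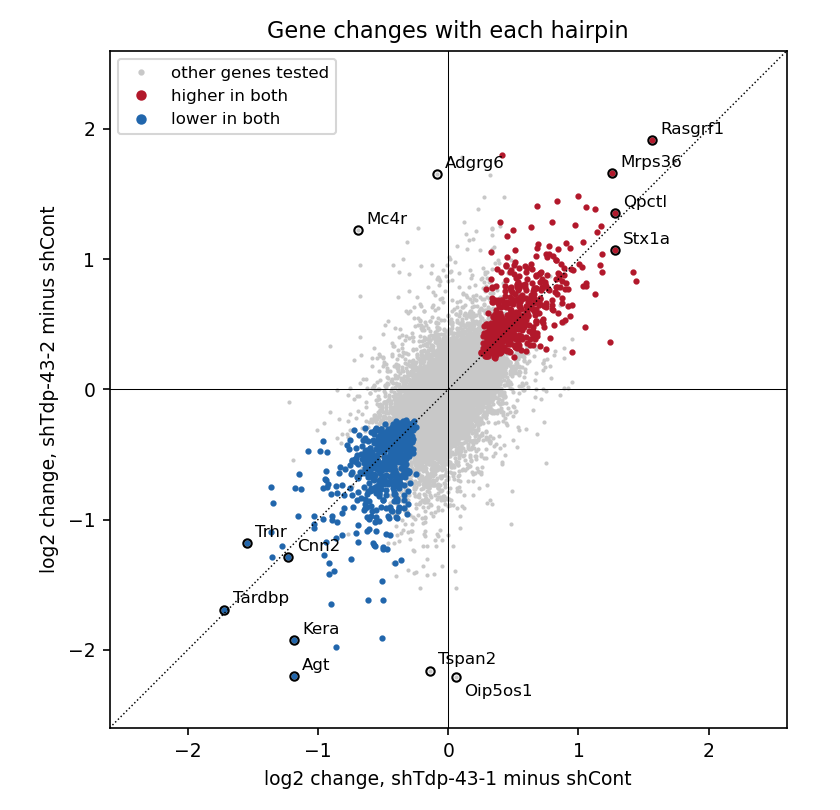
Log2 change of each of 16770 genes with shTdp-43-1 (horizontal) and shTdp-43-2 (vertical) against shCont; red and blue points are the 495 genes higher and 586 lower in both, grey points are the other genes and the dotted line marks equal change. Tardbp lies on the line at -1.72 and -1.69, while Oip5os1, Tspan2, Adgrg6 and Mc4r lie far from it.

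Taken one at a time, shTdp-43-1 changed 1865 genes (865 higher, 1000 lower) and shTdp-43-2 changed 3667 (1301 higher, 2366 lower). Most changes were small: the median size among called genes was log2 0.43 and 0.44, and 44 and 152 of them changed at least 2-fold. The mean of both hairpins changed 3234 genes, 1245 higher and 1989 lower, 50 of them at least 2-fold. With each array centred on its median the splits were 1214 higher and 884 lower for shTdp-43-1, 2178 and 1717 for shTdp-43-2 and 1880 and 1444 for the mean. Quantile normalization of the gene values gave 1793 and 2113 for shTdp-43-2, so that the surplus of lower genes depends on the scaling. Without shCont replicates 1, 2 or 3 the count for shTdp-43-1 was 784, 915 or 1212 and that for the mean 1631, 1903 or 2152; without shTdp-43-1 replicate 2 or 3 the count for shTdp-43-1 was 1013 or 1048.

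The lists are described for the mean of both hairpins minus shCont, as log2 change ± SE with 3 control and 6 knockdown arrays, and every verb of change refers to an adjusted p under 0.05. Over all 16770 genes 19.3% were called in this contrast, 1245 higher and 1989 lower. A count near or below that share does not set a list apart from other genes. A call in this contrast does not mean that the gene was called with each hairpin alone. Among genes with long introns that encode synaptic proteins and bind Tdp-43, 3 of 20 measured members rose and 2 fell (adjusted over the list alone, 4 and 3). The potassium channel partner Kcnip4 rose by 0.40 ± 0.0871, the channel Kcnd2 by 0.33 ± 0.0837 and the kainate receptor Grik2 by 0.28 ± 0.0898, and the adhesion gene Opcml changed by -0.24 ± 0.0694; the calls of Grik2 and Opcml were each kept in 8 of 19 other settings. None of the 20 was called in both hairpins separately by limma, although 7 and 9 had an unadjusted p under 0.05 with shTdp-43-1 and shTdp-43-2. Of 11 genes whose splicing Tdp-43 controls, 2 fell, Tardbp itself and Hnrnpa1 (-0.33 ± 0.0741); adjusted over the list alone the count was the same 2. Of 9 genes that host cryptic exons when Tdp-43 is lost, 1 rose and 4 fell (adjusted over the list alone, 1 and 5). Washc4 changed by -0.98 ± 0.111, Tecpr1 by -0.47 ± 0.0825 and Ift81 by -0.44 ± 0.0895, while Camk1g rose by 0.41 ± 0.0855.

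Of 20 measured genes linked to amyotrophic lateral sclerosis or frontotemporal lobar degeneration, 3 rose and 3 fell (adjusted over the list alone, 3 and 4). Chmp2b, a subunit of an endosomal sorting complex, rose by 0.70 ± 0.0903, C9orf72 by 0.69 ± 0.0765 and Grn, the progranulin gene, by 0.47 ± 0.089, each called with both hairpins. Besides Tardbp, Optn (-0.36 ± 0.0931) and Hnrnpa1 fell, but neither was called with shTdp-43-1 alone (limma adjusted p = 0.279 and 0.311).

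Of 18 genes of the axonal cytoskeleton, Nefm (-0.57 ± 0.0985), Nefl (-0.53 ± 0.079) and Dcx (-0.27 ± 0.0756) fell and the microtubule regulator Stmn4 rose (0.31 ± 0.0623); adjusted over the list alone the count was again 1 higher and 3 lower. Of 19 genes of presynaptic release, 4 rose and 2 fell (adjusted over the list alone, 4 and 2), led by Stx1a (1.18 ± 0.0891), the active zone scaffold Bsn (0.55 ± 0.109), the vesicle protein Sv2b (0.52 ± 0.0725) and the vesicular glutamate transporter Slc17a7 (0.39 ± 0.115). Of 18 glutamate receptor genes, 3 rose and 3 fell (adjusted over the list alone, 4 and 5), among them Grin2a (-0.44 ± 0.132), Grin3a (-0.32 ± 0.0785) and Grik4 (-0.29 ± 0.0879), whose call was kept in 7 of 19 other settings. Of 9 GABA-A receptor genes Gabra3 rose (0.36 ± 0.0686) and Gabra4 fell (-0.27 ± 0.0798, kept in 8 of 19 other settings), the same count as adjusted over the list alone. No glutamate or GABA-A receptor gene was called in the same direction with both hairpins. With shTdp-43-1 alone 1 glutamate receptor gene fell and 0 GABA-A receptor genes were called. With shTdp-43-2 alone 5 and 2 rose and 3 and 2 fell.

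Of 20 voltage-gated channel genes, 3 rose and 3 fell (adjusted over the list alone, 3 and 4); Cacna2d1, a calcium channel subunit, changed by -0.70 ± 0.103, Kcna4 by 0.41 ± 0.104, Kcna1 by -0.38 ± 0.0929 and Cacna1b by -0.35 ± 0.0794. Of 21 synaptic adhesion genes, 4 rose and 1 fell (adjusted over the list alone, 4 and 2), with Ncam2 (0.34 ± 0.0856), Cadm3 (0.33 ± 0.0862), Lrrtm4 (0.30 ± 0.0741) and Cadm1 (0.25 ± 0.0659) among those that rose. No voltage-gated channel or synaptic adhesion gene was called in the same direction with both hairpins. With shTdp-43-1 alone 1 channel gene rose and 1 adhesion gene fell. Axon guidance genes moved in both directions: of 22, 5 rose and 5 fell (adjusted over the list alone, 5 and 6), and 7 were called with both hairpins. The semaphorin receptors Plxna4 (-0.75 ± 0.0893) and Nrp1 (-0.60 ± 0.079) fell, and the ligand Slit3 (0.74 ± 0.0981) and the netrin receptor Unc5d (0.60 ± 0.0947) rose. The median, the mean and camera's direction had different signs for the glutamate receptor (0.0328, -0.00272 and Up), voltage-gated channel (0.08, -0.02 and Up) and synaptic adhesion lists (-0.02, 0.02 and Up), and camera's adjusted p was 0.896, 0.896 and 0.552.

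Among genes induced by neuronal activity, 5 of 16 rose and 1 fell (adjusted over the list alone, 6 and 1). Fosb rose by 0.70 ± 0.217, a call kept in 6 of 19 other settings, the phosphatases Dusp1 by 0.57 ± 0.104 and Dusp6 by 0.56 ± 0.0899, and Egr4 by 0.46 ± 0.075. Camera placed the list above other genes with shTdp-43-1 (adjusted p = 0.0234, and adjusted p = 0.989 with an estimated correlation). In the mean of the hairpins its adjusted p was 0.0756. There camera called it in 3 of 19 other settings: without shTdp-43-2 replicate 1 (adjusted p = 0.0243), without shTdp-43-1 replicate 1 and with the replicate number as a block. Of 17 interferon response genes, 3 rose and 1 fell (adjusted over the list alone, 3 and 1): the chemokine Cxcl10 (0.39 ± 0.122), Psmb8 (0.30 ± 0.0893) and Bst2 (0.30 ± 0.0780) rose and Oasl2 fell (-0.55 ± 0.127). The call of Cxcl10 was kept in 4 of 18 other settings and that of Psmb8 in 7 of 18. With shTdp-43-1 alone 0 of the 17 interferon genes rose and 1 fell, while with shTdp-43-2 alone 3 rose and 1 fell.

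Of 15 p53 targets, 4 rose and 2 fell (adjusted over the list alone, 4 and 3), with Trp53inp1 (-0.67 ± 0.109) and Ccng1 (-0.60 ± 0.0642) lower and Zmat3 (0.53 ± 0.0932) and Ddit4l (0.50 ± 0.12) higher. Of 22 genes of the integrated and endoplasmic reticulum stress responses, Pdia4 (-0.58 ± 0.0872) and Ddit4 (-0.45 ± 0.0808) fell, the same count as adjusted over the list alone. Of 10 heat shock genes 1 fell, Hsph1 (-0.27 ± 0.0746), again also adjusted over the list alone, but with shTdp-43-1 alone 0 of the 10 were called.

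Of 18 genes of cholesterol synthesis 4 rose, each called with both hairpins (adjusted over the list alone, 4). With shTdp-43-2 alone 5 rose and 2 fell. Camera's adjusted p for the list was 0.00911 with shTdp-43-1 and 0.0886 with shTdp-43-2. Idi1, which isomerises isopentenyl diphosphate, rose by 1.04 ± 0.118, the sterol sensor Insig1 by 0.48 ± 0.0806, and the enzymes Sqle by 0.42 ± 0.0722 and Lss by 0.40 ± 0.0916. In the mean of the hairpins this list was the only 1 of 29 that camera called (Up, adjusted p = 0.0307, and adjusted p = 0.994 with an estimated correlation). Its members had a median change of 0.18. The call was absent without shTdp-43-2 replicate 2 and without shCont replicate 3, where 0 lists were called and 6 and 4 had an unadjusted camera p under 0.05, and with arrays centred on their median (adjusted p = 0.0511). Without shTdp-43-1 replicate 1 the activity list was called in its place. With an estimated correlation camera called 0 of 29 lists and 0 had an unadjusted p under 0.05; fry called 0 lists in its directional test, with 8 at an unadjusted p under 0.05, and 24 in its mixed test.

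Among 21 autophagy and lysosome genes Atg7 fell (-0.64 ± 0.0749) and Ulk1 (0.45 ± 0.0899) and Atg12 (0.31 ± 0.0929) rose, the same count as adjusted over the list alone. Of 20 genes of the mitochondrial respiratory chain, Ndufs1 (-0.45 ± 0.0842) and Sdha (-0.20 ± 0.0618) fell (adjusted over the list alone, 1), the call of Sdha being kept in 7 of 19 other settings. Camera placed this list lower with an adjusted p of 0.111, and of 0.0463 and 0.0187 with the dim filter at the 25th percentile and with none. With shTdp-43-2 by itself 8 of the 20 fell (adjusted over the list alone, 10), against 0 with shTdp-43-1, where limma gave 0 an unadjusted p under 0.05. Of 17 glycolysis genes 3 fell (adjusted over the list alone, 2): the glucose transporter Slc2a1 (-0.69 ± 0.0937), Hk2 (-0.49 ± 0.108) and Eno2 (-0.29 ± 0.0935), whose call was kept in 5 of 19 other settings. Of 25 genes for hnRNPs and splicing regulators, 1 rose and 5 fell (adjusted over the list alone, 1 and 5), among them Rbfox1 (-0.43 ± 0.0701), Hnrnpd (-0.35 ± 0.0846) and Elavl4 (-0.30 ± 0.0757). With shTdp-43-1 alone 1 of the 25 rose and 1 fell, and with shTdp-43-2 alone 0 rose and 5 fell. In the same direction with both hairpins, 0 of the 25 were called higher and 1 lower. The autophagy and lysosome list and the glycolysis list had these same counts in both hairpins.

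Markers of cell types that an embryonic cortical culture could hold moved in part. Of 11 markers of excitatory neurons 2 rose and 3 fell (adjusted over the list alone, 2 and 5), with Neurod6 (-0.60 ± 0.0777) lowest and Camk2a (0.36 ± 0.0755) higher. Of 13 markers of inhibitory neurons Gad2 rose (0.67 ± 0.103) and Sst (-0.73 ± 0.112) and Dlx1 (-0.30 ± 0.0829) fell (adjusted over the list alone, 1 and 3). Of 14 astrocyte markers Aqp4, the water channel of astrocytes, fell (-0.51 ± 0.092) and Vim rose (0.32 ± 0.0798), also adjusted over the list alone. Of 11 markers of fibroblasts and pericytes 4 fell (adjusted over the list alone, 4): Dcn (-0.72 ± 0.0792), Fn1 (-0.66 ± 0.160), Pdgfrb (-0.63 ± 0.115) and Rgs5 (-0.62 ± 0.0869). Fewer were called in the same direction with both hairpins. There, 0 excitatory markers were higher and 1 lower, and 1 inhibitory marker was higher and 0 lower. For astrocytes the counts were 0 and 1, and for fibroblasts and pericytes 0 and 2. Of 8 endothelial markers Tek rose (0.24 ± 0.0765; kept in 3 of 18 other settings; adjusted over the list alone, 0), and of 14 markers of cycling progenitors Eomes fell (-0.37 ± 0.0841), also adjusted over the list alone. For 13 markers of the oligodendrocyte lineage and 13 of microglia limma called 0 in any contrast; at an unadjusted p under 0.05 in the mean of the hairpins there were 0 and 0, and with each hairpin 1 and 1 of the first list and 0 and 0 of the second. In both of these lists camera's direction (Up) differed in sign from the mean change (-0.01 and -0.04), with adjusted p of 0.896 and 0.982.

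**Figure D3:**
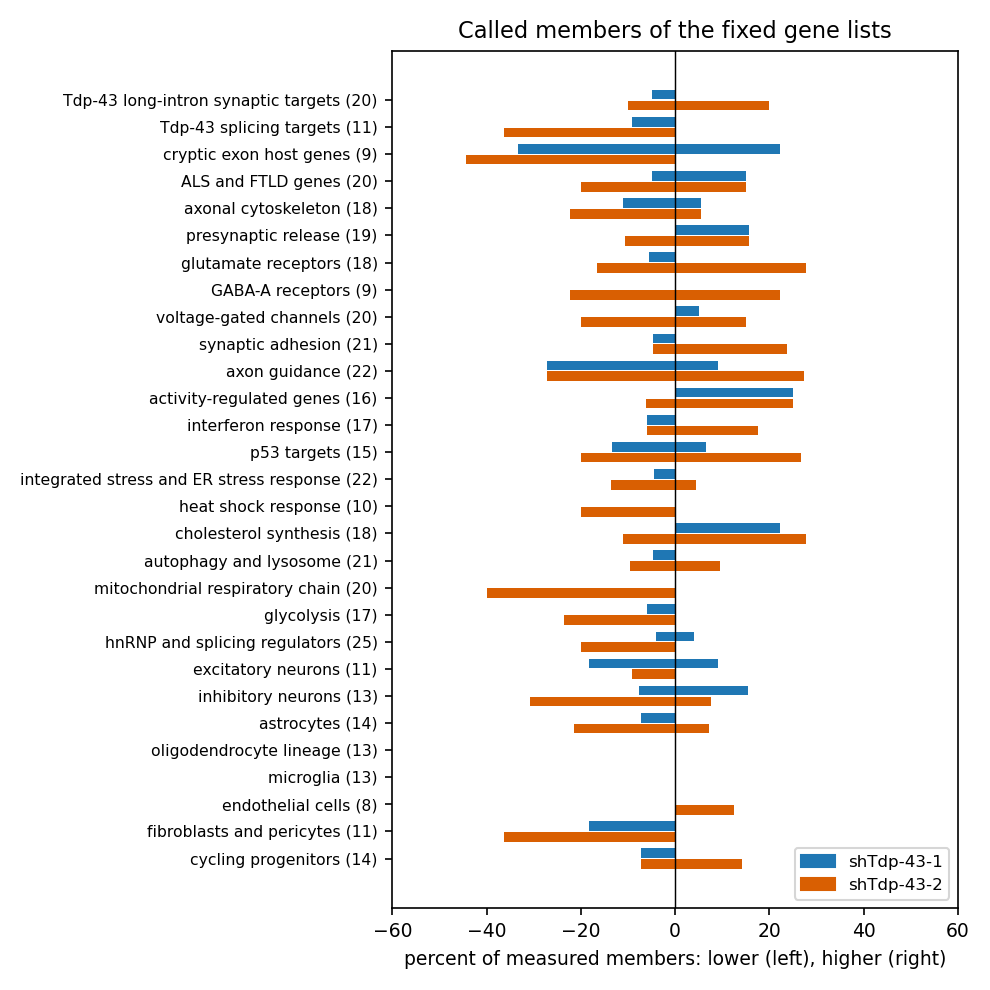
Percent of the measured members of each of 29 gene lists (number measured in brackets) called lower (bars to the left) or higher (bars to the right) with shTdp-43-1 (blue) and shTdp-43-2 (orange) against shCont, at a limma adjusted p under 0.05 over all genes. Over all genes, 11.1% were called with shTdp-43-1 and 21.9% with shTdp-43-2. The mitochondrial respiratory chain has 8 of 20 members lower with shTdp-43-2, and the lists of the oligodendrocyte lineage and of microglia have no bar.

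The hairpins also differed from each other. Oip5os1, a long noncoding RNA, was at a log2 value of 12.04 ± 0.111 (SD, n = 3) in shCont, 12.10 ± 0.157 in shTdp-43-1 and 9.83 ± 0.157 in shTdp-43-2, a difference of -2.27 ± 0.108 (SE) between the hairpins (limma adjusted p = 2.4e-06). Tspan2, a tetraspanin, differed by -2.02, the microtubule-binding Map7d2 by -1.59, the mitochondrial thiolase Acaa2 by -1.52 and the U7 particle component Lsm11 by -1.45, all lower with shTdp-43-2. Higher with shTdp-43-2 were Adgrg6 by 1.74 and Lgals1, which encodes galectin-1, by 1.68, as well as Samd9l by 1.47. The melanocortin receptor Mc4r and the relaxin receptor Rxfp1 moved in opposite directions: Mc4r by -0.69 with shTdp-43-1 and 1.22 with shTdp-43-2, and Rxfp1 by -0.68 and 0.95. In all 1934 genes (11.5% of those tested) differed between the hairpins, 708 higher and 1226 lower with shTdp-43-2, and 69 of them at least 2-fold.

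Among the lists, cycling progenitor markers were higher with shTdp-43-2 than with shTdp-43-1 (camera Up, adjusted p = 0.0145; adjusted p = 0.989 with an estimated correlation), with 3 of 14 called (adjusted over the list alone, 3): Nes differed by 0.79 ± 0.102, Cdk1 by 0.36 ± 0.10 and Hes1 by 0.36 ± 0.089, genes named after their values were seen. Of the mitochondrial respiratory chain 4 of 20 were lower with shTdp-43-2 (adjusted over the list alone, 6), with Ndufs1 at -0.75 ± 0.0972. Dcn (-0.86 ± 0.0914) and Rgs5 (-0.43 ± 0.10), the markers of fibroblasts and pericytes, were lower with shTdp-43-2 too. The calls between hairpins split into 1205 higher and 1126 lower with centred arrays and into 1141 and 1281 with quantile normalization. Without shTdp-43-2 replicate 1, shTdp-43-1 replicate 2 or shTdp-43-1 replicate 3 the count of genes was 964, 1227 or 1253, and 1041 without shTdp-43-1 replicate 2 and shTdp-43-2 replicate 3 together.

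**Figure D4:**
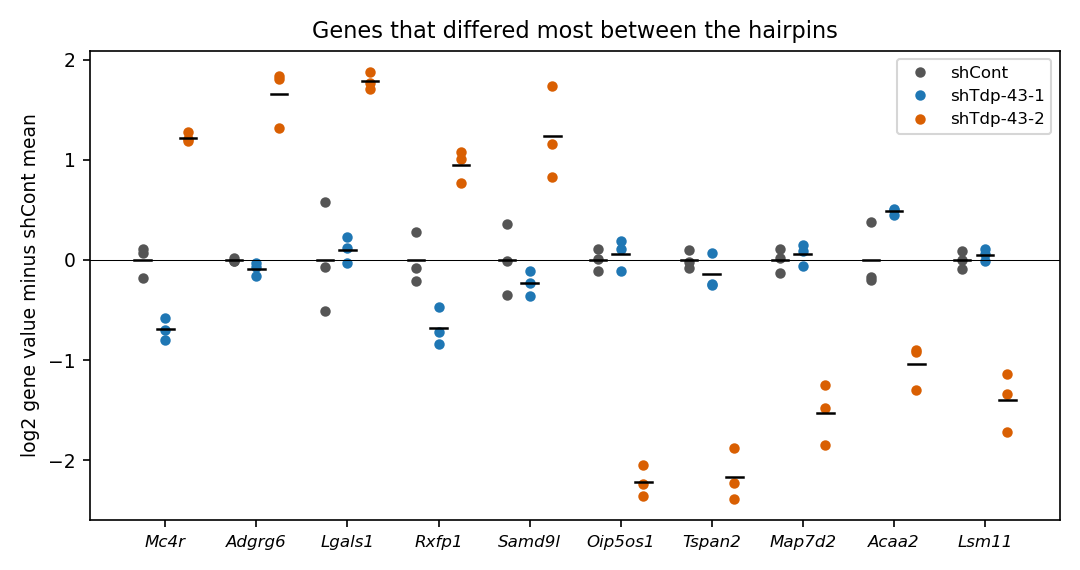
Log2 gene value minus the shCont mean (vertical axis) of the 10 genes with the largest differences between the hairpins, 5 higher and 5 lower with shTdp-43-2; points are arrays (n = 3 per group) and dashes are group means. Mc4r was lower than control with shTdp-43-1 and higher with shTdp-43-2, while Oip5os1 was 0.06 from control with shTdp-43-1 and -2.21 with shTdp-43-2.

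At the level of exons, single probe sets moved apart from the rest of their gene with both hairpins. Probe set 5216450 of Camk2a, the alpha subunit of CaMKII, changed by log2 -2.29 ± 0.183 (SE) against the rest of the gene with shTdp-43-1 and by -2.53 ± 0.183 with shTdp-43-2, from a value of 10.44 ± 0.144 (SD, n = 3) in shCont to 8.77 and 8.16. In Dnm1, which encodes dynamin 1, 6 of 34 probe sets had lower usage in both, led by 4534177 (-1.81 and -1.49). Higher usage was seen for Cemip2 probe set 5085525 (2.21 and 2.13) and for Elk1 probe set 4524358 (1.48 and 1.47). In Slc8a1, a sodium-calcium exchanger, probe set 4782942 had lower usage (-1.68 and -1.42) and 5127034 higher usage (1.61 and 1.56).

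Known Tdp-43 targets were among these genes. In Sort1, the sortilin gene, probe sets 4453253 (1.05 and 1.17), 5130299 (1.03 and 1.15) and 4576227 (0.64 and 0.62) had higher usage, and in Dnajc5 probe set 5415291 did (1.44 and 1.10). Of the hosts of cryptic exons, Usp15 (5616159, 1.12 and 0.97, and 5185796, 0.90 and 0.86), Washc4 (5457190, 1.03 and 1.43) and 2610507B11Rik (5341452, 0.66 and 0.62) had probe sets of higher usage. The Washc4 probe set itself changed by only 0.04 and 0.40, while the gene changed by -0.96 and -0.99. Of the synaptic targets, Nrxn3 had 1 of higher usage (4477627, 1.30 and 0.95) and Lsamp 2 of lower usage (4638350, -0.70 and -0.95, and 4784480, -0.76 and -0.67). Among the probe sets named so far in this paragraph, only that of Dnajc5 was also called in both hairpins with its own spread. A probe set of Tsn, 4700260, passed with shTdp-43-1 alone (1.28, adjusted p = 3.1e-05) and not with shTdp-43-2 (0.72, adjusted p = 0.0508); the difference between hairpins was not tested. At least 1 shared call fell in 3 of 9 cryptic exon hosts, in 2 of 11 splicing targets and in 380 of all 16770 genes (2.27%). In 10000 random draws at the rate of genes with a similar number of probe sets, the p was 0.0072 for the hosts and 0.0459 for the splicing targets, and after adjustment over the 29 lists it was 0.209 and 0.538.

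The rule also named probe sets with higher usage in Cps1 (5422512, 1.82 and 1.83), Hibch (4415995, 1.79 and 1.87), Ranbp17 (5334877, 1.60 and 1.65), Cnn2 (4635417, 1.55 and 1.77), Ankrd63 (5338759, 1.53 and 1.48), Rad51d (5514483, 1.49 and 1.40) and Tarsl2 (5539382, 1.35 and 1.39). Lower usage was seen in Plb1 (4395764, -2.04 and -1.65), Diaph3 (5163642, -1.63 and -1.74), Nrcam (4999666, -1.43 and -1.70), Pdlim5 (5138027, -1.82 and -1.41), Cfap206 (4547451, -1.37 and -1.50), Il12rb2 (4948821, -1.80 and -1.36) and Gng7 (5350724, -1.34 and -1.53). A usage change can come mostly from the rest of the gene: the Gng7 probe set read 11.26 in shCont, 11.31 and 11.24 with the hairpins while the gene rose. Of the 470 shared calls, 109 (23.2%) came from probe sets whose own change was, with each hairpin, less than 0.5 of the usage change in size, among them those of Cps1, Cnn2, Tarsl2, Cfap206, Washc4 and Uros. Small own changes count here too: the Cps1 probe set rose by 0.39 and 0.65 while the gene fell. In 91.5% of the 470 the probe set itself moved in the direction of the usage with both hairpins. The Hibch call rested on 1 control array: in the mean of the hairpins its usage change was 1.83 (adjusted p = 0.00496) with all arrays and 0.01 (adjusted p = 1.00) without shCont replicate 3.

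In all, diffSplice called 1229 probe sets with shTdp-43-1 (638 with higher usage, 591 lower, in 994 genes), 3095 with shTdp-43-2 (1327 and 1768, in 2066 genes) and 470 in the same direction with both (210 and 260, in 380 genes), with 1 called in opposite directions. In simulated data the same step called 103 other probe sets in both beside the 83 of 100 and 100 of 100 changed ones, so that false calls are to be reckoned with among the 470. Both comparisons used the same control arrays, and how many shared usage calls these alone would yield was not estimated. With quantile normalization the first count split into 530 and 889. With each probe set's own spread, chosen after seeing the data, the counts were 13, 375 and 9. The 9 shared by both tests lie in Camk2a, Cemip2, Dnajc5, Dnm1 (5340607 and 5372697), Elk1, Slc8a1 (4782942), Kcnma1 (4972911, 1.32 and 1.38) and Uros (5250760, 1.19 and 1.10), the last pair of genes being named after their values were seen. In the mean of the hairpins 53 of the 470 were also called with their own spread. Without shCont replicates 1, 2 or 3 the shared count was 259, 233 or 312, the count for shTdp-43-1 703, 625 or 754 and that for shTdp-43-2 1724, 1636 or 1943; without shTdp-43-1 replicate 2 or 3 the shared count was 275 or 263 and that for shTdp-43-1 766 or 727; without shTdp-43-2 replicate 2 or 3 the count for shTdp-43-2 was 4768 or 1891.

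**Figure D5:**
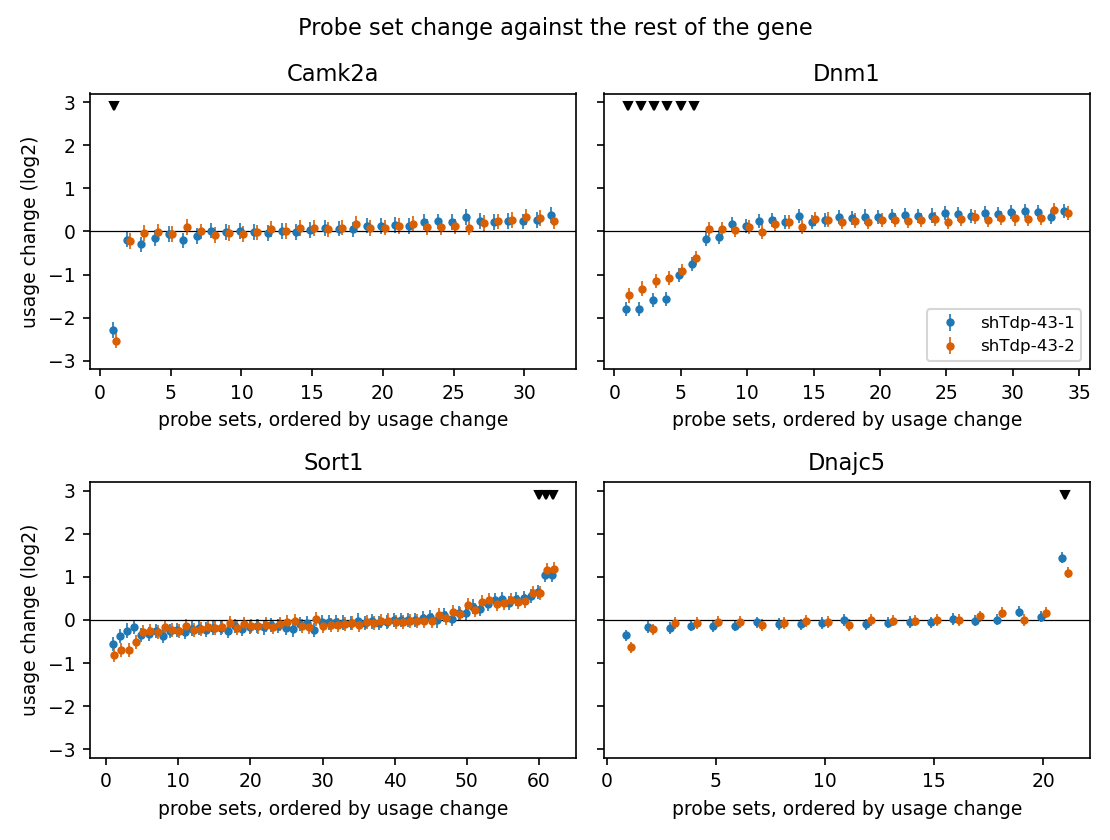
Change of each probe set against the rest of its gene (log2, vertical axis) with shTdp-43-1 (blue) and shTdp-43-2 (orange) in Camk2a, Dnm1, Sort1 and Dnajc5, ordered by size and not by position; bars are the standard error of the fit and triangles mark the probe sets called in both hairpins. In Camk2a 1 of 32 probe sets lies below -2, and in Dnm1 6 of 34 lie apart from the others.

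Tested one by one with no use of gene names, 5050 of 628416 probe sets were called in the mean of the hairpins, 2338 higher and 2712 lower. With the dim filter at the 25th and 75th percentile the count was 964 and 14479, and with trend and robust 16388. It also depended on nearly every array: the count was 51, 0 or 466 without shCont replicate 1, 2 or 3 (62081, 69691 and 66397 at an unadjusted p under 0.05), 3251, 1811 or 1253 without shTdp-43-1 replicate 1, 2 or 3, and 2046 or 2832 without shTdp-43-2 replicate 1 or 3. It was 3897 without shTdp-43-2 replicate 2.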

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

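The tests against a deeper knockdown with one hairpin, against 2 deviating arrays and against RNA outside named exons were chosen only after the results were seen. The hairpins lowered Tardbp alike, yet 1934 genes differed between them. The largest differences, shTdp-43-2 minus shTdp-43-1, were Mc4r 1.91, Adgrg6 1.74, Lgals1 1.68, Rxfp1 1.63 and Samd9l 1.47 upward and Oip5os1 -2.27, Tspan2 -2.02, Map7d2 -1.59, Acaa2 -1.52 and Lsm11 -1.45 downward. A difference in Tardbp mRNA beyond the 95% interval of -0.38 to 0.43 is argued against by the measured 0.0262. A smaller difference within that interval stays open, and Tdp-43 protein was not measured. The 2 arrays that deviate together (shTdp-43-1 replicate 2 and shTdp-43-2 replicate 3, r of deviations 0.68) are not the whole cause, since 1041 genes differed without them. Effects of each hairpin's own sequence on other transcripts, or a difference in infection or culture, could also produce this pattern and stay open as untested.

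Probe sets without a gene name were brighter on the shTdp-43-1 arrays: the dim ones were shifted by log2 0.13 ± 0.0196 (SD, n = 3) against the mean of the controls, and by 0.03 ± 0.0371 (SD, n = 3) with shTdp-43-2, while single controls lay between -0.02 and 0.02. A higher background on those arrays may account for the dim shift, as dim named probe sets moved by at least 74.6% as much on each shTdp-43-1 array. Bright unnamed probe sets (control mean at or above 6.07) were up by 0.05, 0.12 and 0.11 on these arrays, and bright named ones moved by 0.01, -0.03 and -0.03. The same kind of gap was seen on shTdp-43-2 replicate 3 (0.05 and -0.08). Whether background could account for the bright shift cannot be told, as the 2 sets were not matched for brightness. On shCont replicate 1 the median of all probe sets with 1 gene symbol was 8.50 and that of all unnamed ones 5.50. Loss of Tdp-43 raising RNA outside named exons is not settled by the tables, for only 26.4% of the shift was seen with shTdp-43-2 at a similar loss of Tardbp mRNA. Of the unnamed probe sets 1182 of 370619 (0.319%) were called in the mean of the hairpins, 490 higher and 692 lower, against 3868 of 257797 named ones (1.50%).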

How the results depend on the processing

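Leaving out 2 arrays, using each probe set's own spread and following the named items through every setting were chosen only after the result was seen. Tardbp fell in every setting: leaving out single arrays gave -1.89 to -1.54 with shTdp-43-1 and -1.87 to -1.53 with shTdp-43-2. All 29 genes named besides Tardbp for calls in both hairpins kept them, in the same direction, in every setting in which they were measured, and the 10 named between the hairpins kept theirs. Of 82 named list members 44 kept the call in the mean in every setting; Tek kept it in 3 of 18, Cxcl10 in 4 of 18, Eno2 in 5 of 19, Fosb in 6 of 19, Psmb8 in 7 of 18, Grik4 and Sdha in 7 of 19 and Grik2, Opcml and Gabra4 in 8 of 19. Of the 20 exon probe sets named by the rule 4 kept the call in both hairpins in every setting, those of Camk2a, Cemip2 and Elk1 and 4782942 of Slc8a1. Leaving out single arrays gave 784 to 2224 genes with shTdp-43-1, 2484 to 3894 with shTdp-43-2, 491 to 1009 in both, 964 to 1926 between the hairpins, 1631 to 3487 in the mean and 0 to 2 lists. It gave 625 to 1630 usage calls with shTdp-43-1, 1636 to 4768 with shTdp-43-2, 233 to 575 in both and 0 to 3897 probe sets in the mean.

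Without the 2 arrays that deviate together there were 710 genes in both, 1041 between the hairpins, 1917 usage calls with shTdp-43-2, 294 in both and 585 probe sets in the mean. The dim filter at the 25th percentile gave 2 lists (cholesterol synthesis and the mitochondrial respiratory chain), 1993 usage calls with shTdp-43-1 and 964 probe sets, and the 75th gave 621 usage calls with shTdp-43-1, 306 in both and 14479 probe sets. No filter gave the same 2 lists, centred arrays 0 (4 at an unadjusted camera p under 0.05), camera with an estimated correlation 0 (0 unadjusted), fry directional 0 (8 unadjusted) and fry mixed 24. Trend and robust gave 16388 probe sets. The own spread gave 13 usage calls with shTdp-43-1, 375 with shTdp-43-2 and 9 in both. For all of these the cause was not tested.

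With the replicate number as a block there were 2353 genes with shTdp-43-1, 4107 with shTdp-43-2, 1314 in both, 2338 between the hairpins and 3691 in the mean, 2 lists (cholesterol synthesis and, at an adjusted p of 0.0162, activity-regulated genes), 2644, 5035 and 1018 usage calls and 3044 probe sets. The main fit, fixed before the data were examined, took the samples as unpaired. Whether the replicate number links samples across groups is not known here. The deviations do not settle it: the highest r between groups, 0.681, was of a pair with different numbers, but 6 of 9 same-number pairs had deviations correlated over 0.1. These were all pairs of replicate 1 (r = 0.399, 0.335 and 0.593) and of replicate 3 (0.320, 0.128 and 0.152), while those of replicate 2 were -0.0838, 0.0406 and -0.383. As a hint from the data that part of the arrays share a replicate effect, 5 of 9 arrays correlated best with an array of their own number. The cause was not tested.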

Other observations

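No test in this part was chosen only after the result was seen, but the genes of the next paragraph were.

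Some genes had several probe sets with changed usage in both hairpins. In Mcf2l 8 of 55 probe sets were called, 1 higher and 7 lower, while the gene rose by 0.91 and 0.81; the 7 lower ones themselves moved by less than 0.5 of their usage change with each hairpin. In Ryr1, a calcium release channel, 6 of 93 were called, 1 higher and 5 lower, led by 4678778 (-1.16 and -1.70), and the gene changed by -0.46 and -0.59. In Syn3, a synapsin, all 5 called of 27 had lower usage (5240921, -0.79 and -1.14) while the gene rose by 0.54 and 0.42, and in the spectrin gene Sptan1 all 4 called of 60 did (4388248, -1.18 and -1.12). Among splicing regulators Celf1 had a probe set of higher usage (4719591, 1.15 and 1.26) and Celf2 one of lower usage (5583475, -0.85 and -0.68). Among synaptic genes Ncam2 had 1 of lower usage (5440468, -1.16 and -0.78) and Syt1 1 of higher usage (4962303, 0.51 and 1.04).

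Among the 470 usage calls shared by both hairpins, 109 came from a probe set whose own change was less than 0.5 of the usage change with each hairpin, as in Gng7 and Tarsl2, though in 91.5% of the 470 the probe set moved in the direction of the usage. Probe sets at the dim or bright end of the scale might fail to respond. Of the 109, 25 (22.9%) lay in the dimmest or brightest 10%, against 115 of the other 361 (31.9%; Fisher exact p = 0.0939), which cannot tell. Nearly all of these were dim: 24 of the 25 and all 115 lay in the dimmest 10% of the tested probe sets. In both sets of shared calls, dim probe sets were thus more frequent than the 10% they make up among all tested. Probe sets that also measure another transcript, and exons kept at a constant level, stay open as untested.

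The counts were set beside those from other groupings of the same arrays. For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05: the real grouping was 1 of 10 with as many calls for genes in shTdp-43-1 (1865, highest other 0), in shTdp-43-2 (3667, highest other 0) and between the hairpins (1934, highest other 0; at an unadjusted p under 0.05, 4252 and at most 4103), and for usage in shTdp-43-1 (1229, highest other 590) and shTdp-43-2 (3095, highest other 2246). Over 100 groupings of all arrays, 2 had as many genes in both hairpins (1081, highest other 1226) and 1 as many in the mean (3234, highest other 3216); the highest other keeps the real groups with shTdp-43-2 as the reference. For the lists 95 of 100 had at least as many calls (1, highest other 15), so that the call of the cholesterol list could arise from other groupings of these arrays. For usage in both 2 of 40 had as many (470, highest other 1601), so chance is not excluded for this count. That grouping has replicate 1 of all 3 groups as its reference. The grouping of all arrays by replicate number, with replicate 3 as the reference, gave 8 usage calls and 15 lists. This 8 cannot speak against a deviating replicate 1. A shared call there needs replicates 1 and 2 to differ from replicate 3 in the same direction. The 1601 calls point to a structure of the arrays, which could add to the real count. Its source stays open, though the deviations of all replicate 1 pairs were correlated (r = 0.399, 0.335 and 0.593). With the replicate number as a block the shared usage calls were 1018. For single probe sets 1 of 40 had as many (5050, highest other 490).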
